A study of Camellia sinensis with 32 samples.

How the data were processed

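Leaves of 2-year-old plants of the tea cultivars Longjing43 (LJ, susceptible) and Zhongcha108 (ZC, resistant) were sampled 7 days after mock treatment (CK), inoculation (Cg), caffeine (CN) or both (CgCN). The labels give 3 small RNA libraries for each of the 8 groups and 1 degradome library for each condition, which has no replicate. The labels name a HiSeq 2500 and a HiSeq 4000. The design text speaks of 3 independent replicates but does not say that they come from separate plants, so p-values measure only the spread between these samples. Titles and characteristics of the degradome samples conflict in the labels, and samples were grouped by their characteristics.

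The authors mapped small RNA reads to miRBase hairpins of selected species and to the genome and applied hairpin criteria, per the file headers; the program, its version and the genome build are not given in the sources used here. The raw columns of the miRNA table hold expected counts, in which the authors divided the reads of a mature sequence evenly over its loci, so that 19.3% of the deposited values are not whole numbers. The norm columns hold a deposited signal, which the authors made by multiplying the raw columns by 1 constant per library (0.521 to 1.415); how the constants were found is not stated. In the degradome tables the deposited raw columns are read counts at a cleavage site, and the Normalized columns are expected counts, read counts that the authors divided over transcripts. Their TPB columns are a deposited signal scaled by 1 constant per library. The deposited alignment score (0 to 4, a penalty) and category (0 to 4) come from the authors, as do the p-values (chi-square and Fisher tests between a pair of libraries). Lengths in nt and positions of cleavage sites, other values of the deposited tables, were used as given by the authors.

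The miRNA table had 983 lines below its header, of which 14 were emptied and are not analysed here, leaving 969. These held 793 distinct sequences, 171 of them on more than 1 line (at most 4), always with equal values, and each sequence was kept once. Counts were rounded to whole numbers. Library totals over distinct sequences were 119149 to 470458, and over all lines 167628 to 611929. At these depths 3 counts over a group corresponded to 4.26 to 6.40 CPM, the floor below which a miRNA at 0 in a group cannot be placed.

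Expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, edgeR's default expression filter (477 miRNAs of 56 families kept), robust quasi-likelihood fits and 1 model of 8 group means for all 24 libraries. Adjusted p-values are Benjamini-Hochberg over the 477 miRNAs of a comparison, with a threshold of 0.05. The common dispersion was 0.563. Of the tested miRNAs 26 share their counts with another, in 12 patterns, and are not independent calls. Comparisons were each treatment with mock and the combination with inoculation, per cultivar; ZC with LJ at mock; the difference between cultivars in each response; and the departure of the combined treatment from the sum of its parts. The contrasts of ZCCN with LJCN and of ZCCgCN with ZCCN were added after the data were seen. On simulated data with 200 changed miRNAs the LJ inoculation contrast recovered 3.7, 42.6, 62.5 and 66.7% of changes of 2-, 4-, 8- and 16-fold, with 3 unchanged miRNAs among 89 calls. The mock cultivar contrast recovered 6.1, 22.4, 57.4 and 56.4%, with 2 unchanged among 74.

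Before the values were seen, 12 lists of families were fixed from known functions: auxin signalling, copper and laccase, NBS-LRR targeting, small RNA machinery, nutrient starvation or phloem-mobile, juvenile leaf or SPL-targeting, adult leaf or AP2-targeting, MYB and TCP targeting, phenylpropanoid MYB and TAS4, leaf development, NF-YA targeting and Arabidopsis PAMP-responsive. They were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, in limma 3.58.1, adjusted over lists and comparisons of a kind. miRNAs named in the text are those with the largest log2 fold changes among calls with a mean of at least 10 CPM in either group and no overlap between groups (up to 10 each way against mock and between cultivars, up to 5 each way elsewhere and without the overlap condition), the most abundant member of each list and the 5 most abundant miRNAs. Where fewer than 5 passed, the 5 smallest p-values are given as values.

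Length shares were compared by two-sided exact permutation tests. Sequences that differ by 1 base from a sequence at least 3 times as abundant were listed by the position of the difference, and libraries were put in a high or low class by the share of position 9 variants (10% as the border, chosen after the data were seen). Degradome pairs are distinct combinations of miRNA sequence and transcript, kept once per comparison at the site with the authors' smallest p. They have exact binomial intervals for shares and were matched to expression by sequence (301 of 307 miRNA sequences). Transcript names come from the deposited annotation only. Alternatives tried were DESeq2 1.42.0, limma voom, other scalings (RLE, upper quartile, total count, the authors' constants), other filters, the replicate number as a block, other units (all lines, 20 to 22 nt only, sums by family or over loci), fits of single comparisons and fits without each library. Added after the data were seen were fits without position 9 variants, with the library class as a term, and with only the LJCgCN library of the low class. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.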

Results

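Small RNAs were sequenced from leaves of 2 tea cultivars, Longjing43 (LJ), which is susceptible to anthracnose, and Zhongcha108 (ZC), which is resistant. Leaves were taken 7 days after mock inoculation (CK), inoculation with the anthracnose fungus Colletotrichum gloeosporioides (Cg), exogenous caffeine (CN), or inoculation together with caffeine (CgCN). Each of the 8 groups held 3 libraries, 24 in all, and 1 degradome library per condition, 8 in all, recorded the 5′ ends of cleaved transcripts. The miRNA table held 793 distinct mature sequences, of which 376 carried names of known miRNAs from 79 families and 417 were predicted candidates (names starting with PC). Counts summed over the distinct sequences ranged from 119149 to 470458 per library. Levels are given below as CPM (counts scaled by TMM factors to a common library size), as group mean ± SD over n = 3 libraries. Adjusted p-values (Benjamini-Hochberg) come from edgeR's quasi-likelihood test on 477 miRNAs. A group in which every library was at 0 had a floor of 4.26 to 6.40 CPM, set by 3 counts over the group. Folds against such a group are lower bounds from that floor.

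miRNAs of 21 nt held 69.5% of the counts on average (60.4 to 83.9% per library). ppe-miR166a, a member of the family that targets class III HD-ZIP leaf polarity genes, was the most abundant sequence over all libraries. The most abundant sequence of each library held 27.2% of its counts on average. It was mdm-miR535a in LJCgCN replicate 3 and ZCCN replicate 2 and ppe-miR166a in the others. At mock, 22 nt miRNAs held 23.05% ± 1.84 of the counts in LJ and 15.1% ± 6.38 in ZC (SD, n = 3), and 20 nt miRNAs held 0.946% ± 0.0551 and 2.42% ± 1.39. Under caffeine, 20 nt miRNAs held 2.45% ± 1.05 in LJ. In these 3 contrasts and in 2 others of the 45 tested (20 and 24 nt miRNAs in LJCgCN against LJCK) all libraries of one group lay above all of the other, where chance gives 10%. The two-sided exact permutation p was 0.1 in each, the smallest that 3 libraries against 3 allow.

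The libraries also differed in a feature that followed neither cultivar nor treatment alone. In the table, 66 sequences differed by a single base at position 9, counted from the 5′ end, from a sequence at least 3 times as abundant; the next most frequent position had 15. These position 9 variants held 14.7 to 22.1% of the summed counts of variant and abundant partner in 8 libraries (all of ZCCK, all of ZCCg, LJCgCN replicates 1 and 3), and 0.60 to 2.34% in the other 16. Variants at other positions held 4.52 to 13.7% and 4.09 to 12.4% in the same libraries. The stu-miR482a-3p pair alone ranged from 20.4 to 30.5% in the 8 libraries and from 0.17 to 1.13% in the others. The grouping was defined from the data, and it separates ZCCK and ZCCg fully from ZCCN, ZCCgCN, LJCK, LJCg and LJCN. In contrasts across it the group difference and this feature cannot be told apart. Of the 477 tested miRNAs 41 were position 9 variants by this rule, and each one of these named below is given as such. A further 12 carry a substitution at position 9 in their name, relative to the database sequence, without meeting the rule, and are counted with the other miRNAs. Of these, ptc-MIR166n-p5_1ss9TC, gma-MIR167k-p3_3ss9CA21TG22AG, mdm-miR482a-3p_2ss9CG21TG, aly-miR165a-3p_R+1_1ss9GC, gma-miR171j-5p_2ss8CT9TC, hbr-miR398_2ss9CT21GC and hbr-MIR6173-p3_3ss9TA17AG18GC are named below. The last stood at 102 to 643 CPM in the 8 libraries and at 0 to 31.9 in the others, so its changes cannot be told apart from the library class either. Group means of mdm-MIR482c-p3_2ss12TA22TC, also named below, were higher in ZCCK and LJCgCN than in LJCK, LJCg, ZCCN and ZCCgCN. Its changes across the classes, and those of gma-MIR167k-p3_3ss9CA21TG22AG, cannot be told apart from the library class.

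**Figure D1:**
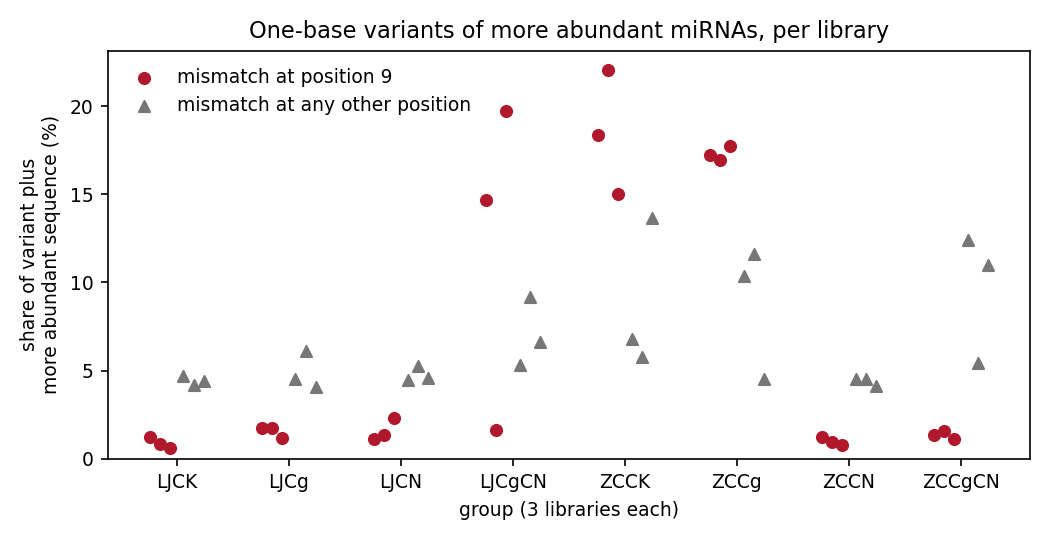
Share (%) that one-base variants held of the summed counts of variant and more abundant sequence, for each of the 24 libraries by group (3 points per group and kind); circles are variants at position 9 and triangles variants at any other position. Circles lie between 14.7 and 22.1% in 8 libraries and between 0.60 and 2.34% in the other 16.

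The inoculated leaves of each cultivar were first set against mock, the contrast that asks which miRNAs respond to the fungus. No miRNA passed the test in either cultivar, so the values that follow describe the smallest p-values. In LJ, mtr-miR390, which triggers the trans-acting siRNAs that silence auxin response factors, stood at 6555 ± 4499 CPM after inoculation and 954 ± 279 at mock (log2 fold change 2.78, SE 0.79, adjusted p = 0.252). The candidate PC-3p-4889_2585 stood at 170.8 ± 67.7 against 701 ± 39.4 CPM (−2.03, SE 0.51, adjusted p = 0.252). PC-5p-81222_156 was at 0 after inoculation and at 76.0 ± 13.9 CPM at mock, at least 15.2-fold apart. The other pair, mtr-miR390_1ss9GC and mtr-miR164a_1ss9CA, were position 9 variants with log2 fold changes of 3.40 and 2.21. In ZC, PC-3p-15934_1146 was at 0 against 43.8 ± 18.1 CPM at mock, PC-3p-36356_497 at 34.1 ± 29.5 against 253 ± 17.8, PC-5p-60986_244 at 0 against 48.8 ± 51.0, PC-5p-44064_389 at 29.3 ± 29.0 against 481.7 ± 261, and PC-5p-557_8339 at 3997 ± 354 against 1728 ± 429.9 (adjusted p from 0.137 to 0.153). ath-miR858a_L-1R+1_1, whose family silences R2R3 MYB regulators of flavonoid synthesis, stood at 7383 ± 3206 CPM in inoculated and 14135 ± 6054 in mock LJ leaves, and at 9954 ± 5134 and 4588 ± 1990.2 in ZC (adjusted p = 0.645 and 0.768).

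Of the auxin list 8 of 21 members had a higher fitted level in inoculated LJ leaves, 2 of them past the threshold when adjusted over the list alone and 0 over all miRNAs (camera adjusted p = 0.993). edgeR called 0 miRNAs in LJ, with 35 at an unadjusted p under 0.05, while DESeq2 called 10 and limma voom 1. Data were simulated from means over all 24 libraries, with 200 of the 477 miRNAs changed. On these the test of inoculated against mock LJ leaves recovered 42.6% of 4-fold and 3.7% of 2-fold changes. Contrasts with fewer changed miRNAs, the inoculation of ZC and the cultivar difference in this response were not simulated. In ZC edgeR called 0, with 30 at an unadjusted p under 0.05, DESeq2 12 and voom 0; without ZCCg replicate 1 edgeR called 2. No overlap between groups was seen for 17.2% of the tested miRNAs in LJ and 11.3% in ZC, where chance gives 10%. The difference between the cultivars in this response gave 0 calls by edgeR (28 at an unadjusted p under 0.05, DESeq2 5, voom 0, and 2 without ZCCg replicate 1). Its smallest p-values were those of PC-3p-15934_1146 (adjusted p = 0.339), then of gma-miR6300_L-1R+8, vvi-MIR319b-p3_2ss6AT21CA, PC-3p-42752_405 and ptc-miR6478_1ss21GA (0.536 each); miR858a had a difference of 2.05 (SE 0.73, adjusted p = 0.536).

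Caffeine alone asks which miRNAs respond to the compound without the fungus. In LJ leaves 3 miRNAs rose and 2 fell. mtr-miR168b_R-1, a form of the miRNA that targets ARGONAUTE1, rose from 37.4 ± 15.8 to 4798 ± 5696 CPM (log2 fold change 6.97, SE 1.12, adjusted p = 0.00172). gma-miR403a_R-1_1ss20TC, from the family that targets ARGONAUTE2, rose from 40.3 ± 24.0 to 1659 ± 1623 CPM (5.36, SE 1.02, adjusted p = 0.00496), with overlapping libraries. gma-MIR167k-p3_3ss9CA21TG22AG was at 0 in mock and at 238 ± 224 CPM under caffeine, at least 41.3-fold higher (adjusted p = 0.0112). PC-5p-2701_3616 fell from 3653 ± 421 to 322 ± 77.5 CPM (−3.50, SE 0.68) and PC-3p-85_54490 from 21626 ± 6287 to 5345 ± 1883 (−2.02, SE 0.39), both with an adjusted p of 0.00496. The last pair are the arms of one predicted hairpin, on the plus strand of Scaffold11162 from 171069 to 171172.

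Of the 12 small RNA machinery miRNAs (families miR162, miR168 and miR403) 11 had a higher fitted level under caffeine in LJ, 2 of them called and 6 called when adjusted over the list alone. camera gave this list an adjusted p of 0.000341, with an adjusted p of 0.995 under an estimated correlation and of 0.172 from fry. The full-length mtr-miR168b stood at 8767 ± 6560 against 2521 ± 298 CPM (adjusted p = 0.104), while stu-miR162a-3p, from the family that targets DICER-LIKE1, stood at 6396 ± 394 against 6417 ± 1629. Of the copper list, whose families target superoxide dismutase, plantacyanin and laccase genes, 2 of 9 members were higher and 2 passed when adjusted over the list alone. These were mtr-miR398a-3p at 13.7 ± 11.9 against 9052 ± 4551 CPM and mtr-miR408-3p_L-1R+1 at 142 ± 118 against 5511 ± 4303 (both 0.139 over all miRNAs; camera adjusted p = 0.0765, 0.995 with an estimated correlation). mtr-miR159a, which targets GAMYB genes, stood at 30669 ± 1909 against 17234 ± 5004 CPM (adjusted p = 0.374). Its MYB and TCP list had 6 of 8 members higher (camera adjusted p = 0.0804). The called members were both forms lacking the last base at the 3′ end. Of the 12 pairs of a longer and a shorter form compared, the shorter lay above all LJCK libraries in both LJCN replicates 1 and 2 in 5, these 2 among them, and not in 7. That of ath-miR858a_L-1R+1_1 held 21, 14.2 and 0.997% in LJCN replicates 1, 2 and 3, and that of mtr-miR396b-3p_2ss7TG8AG 24.1, 20.9 and 7.7%. All 5 calls stayed inside the low class of libraries. They became 3 without LJCK replicate 2, LJCK replicate 3 or LJCN replicate 2, and 11 without LJCN replicate 3, in which the 20 nt form held 2.44% of miR168b against 40.6 and 36.1% in the other caffeine libraries of LJ.

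In ZC leaves caffeine gave 29 calls, 2 up and 27 down, and 17 of those that fell were position 9 variants (Fisher's exact p = 5.9e-13, on a class defined from the same libraries). gma-miR6300 rose from 291 ± 192 to 1827 ± 1310 CPM (2.65, SE 0.69, adjusted p = 0.028) and its longer form gma-miR6300_L-1R+8 from 123 ± 79.6 to 699 ± 509 (2.51, SE 0.74, adjusted p = 0.0452); both lie outside the naming rule and were chosen after their values were seen. rgl-miR7972_1ss14TG was at 1211 ± 244 CPM at mock and 0 under caffeine, at least 208-fold lower (adjusted p = 0.0234). gma-MIR167k-p3_3ss9CA21TG22AG fell at least 41.5-fold from 242 ± 96.3 CPM (adjusted p = 0.00813) and hbr-MIR6173-p3_3ss9TA17AG18GC at least 44.8-fold from 261 ± 148 (adjusted p = 0.0131). The position 9 variants named by the rule, PC-5p-1520_4860 (at least 881-fold lower), the MIR4995 variants (at least 283-, 206- and 43.0-fold), a pair of MIR5368 variants with equal counts (at least 47.7-fold) and gra-MIR8757b-p5_2ss9TA17GC (at least 34.5-fold), were all at 0 under caffeine. mtr-miR168b_R-1, which rose in LJ, fell from 1105 ± 409 to 99.0 ± 26.2 CPM (−3.47, SE 0.95, adjusted p = 0.0385), and mdm-MIR482c-p3_2ss12TA22TC from 1957 ± 159.4 to 31.4 ± 36.1 (−5.93, SE 1.17, adjusted p = 0.0066); these were also chosen after their values were seen. The 20 nt form held 29.6 to 47% of miR168b in all 8 libraries of the high class, and 2.71 to 6.44% in the ZCCN libraries, 3.86 to 4.81% in ZCCgCN and 2.29% in LJCgCN replicate 2. Its fall in ZC thus went with the library class and cannot be assigned to caffeine.

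By list, 0 of 9 copper miRNAs had a higher fitted level under caffeine in ZC, 7 passed when adjusted over the list alone and 0 over all miRNAs (camera adjusted p = 0.1637); hbr-miR398_2ss9CT21GC stood at 286 ± 222 against 8215 ± 11398 CPM (adjusted p = 0.132). Of the leaf development list 7 of 37 were higher and 2 fell, both position 9 variants. In the phenylpropanoid list 7 of 9 were higher (camera adjusted p = 0.0804, 0.995 with an estimated correlation), with ath-miR858a_L-1R+1_1 at 8842 ± 1833 against 4588 ± 1990.2 CPM (adjusted p = 0.293). The count of 29 became 2 without ZCCN replicate 1, 5 without ZCCN replicate 3, 15 without ZCCN replicate 2 and 11 without ZCCK replicate 3. It was 3 when position 9 variants were left out before the fit and 1 with the library class as a term, a term whose effect is estimated only from the LJCgCN libraries.

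The caffeine response differed between the cultivars for 21 miRNAs, 2 with a higher log2 fold change in ZC and 19 with a lower one, 11 of them position 9 variants. Both arms of the Scaffold11162 hairpin that fell in LJ stood near their mock level in ZC. PC-5p-2701_3616 was at 1335 ± 558 CPM under caffeine and 1155 ± 649.7 at mock in ZC, a difference of 3.71 on the log2 scale (SE 0.90, adjusted p = 0.0192). PC-3p-85_54490 was at 11871 ± 616 and 11998 ± 1756 (difference 2.00, SE 0.53, adjusted p = 0.0343). gma-MIR167k-p3_3ss9CA21TG22AG moved in opposite directions, from 0 to 238 ± 224 CPM in LJ and from 242 ± 96.3 to 0 in ZC (adjusted p = 0.000435). Its rise in LJ lay within the low class, but its fall in ZC crossed the library classes and cannot be told apart from them. The other named miRNAs with a difference were mdm-MIR482c-p3_2ss12TA22TC (adjusted p = 0.00228) and the position 9 variants gma-miR394a-5p_1ss9CA, gma-MIR4995-p5_2ss9TA21GC and gma-MIR4995-p5_2ss9GC20GC (0.00348, 0.0204 and 0.0184). The fall of mdm-MIR482c-p3_2ss12TA22TC in ZC went with the library class. mtr-miR159a had a difference of −1.77 (SE 0.54, adjusted p = 0.0662); of its list 1 of 8 had a positive difference and 1, mtr-miR159a_1ss20TC, passed (fry adjusted p = 0.0054, camera 0.229). The count was 8 without ZCCN replicate 1, 12 without LJCK replicate 2, and 11 without LJCK replicate 3 or LJCN replicate 3.

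Inoculation with caffeine was compared with mock and with inoculation alone, which asks what caffeine adds to the infected leaf. In LJ 11 miRNAs rose against mock and 0 fell (edgeR; 72 at an unadjusted p under 0.05), and 8 of them were position 9 variants. The other 3 were mdm-MIR482c-p3_2ss12TA22TC, from a family that targets NBS-LRR resistance genes, at least 129.6-fold higher (746 ± 625 CPM against 0, adjusted p = 0.00436), hbr-MIR6173-p3_3ss9TA17AG18GC, at least 26.3-fold (151 ± 153 against 0, adjusted p = 0.0293), and rgl-miR7972_1ss14TG, at least 117-fold with overlapping libraries (adjusted p = 0.0441). These 3 also stood higher in ZCCK, of the high class, than in ZCCN and ZCCgCN. LJCgCN replicates 1 and 3 are of that class, so the rise cannot be told apart from it. Named position 9 variants were gma-miR394a-5p_1ss9CA (at least 90.8-fold, adjusted p = 0.0177), a pair of MIR5368-p5 variants with equal counts (4.92, adjusted p = 0.0181), mtr-miR164a_1ss9CA (2.90, SE 0.66, adjusted p = 0.0181) and mtr-miR166g-5p_1ss9GC (2.18, SE 0.45, adjusted p = 0.0177). Of the leaf development list 33 of 37 had a higher fitted level, 2 were called, both position 9 variants, and 4 passed when adjusted over the list alone (camera adjusted p = 0.0442, 0.995 with an estimated correlation). The count was 21 without replicate 2, 4 without replicate 1, 5 without replicate 3, 1 without LJCK replicate 1 or 2, and 0 without LJCK replicate 3.

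Against inoculation alone, LJCgCN had 3 calls, all up. mdm-MIR482c-p3_2ss12TA22TC stood at 746 ± 625 against 19.2 ± 16.9 CPM (5.25, SE 1.15, adjusted p = 0.0347); PC-3p-283_14063 (4.39, SE 0.95) and mtr-miR166g-5p_1ss9GC (2.17, SE 0.45), both with an adjusted p of 0.0342, were position 9 variants. gma-miR394a-5p_1ss9CA and rgl-miR7972_1ss14TG had an adjusted p of 0.0602, the latter at 674 ± 608 CPM against 0, at least 135-fold apart. All 8 NF-YA-targeting miR169 members had a higher fitted level (camera adjusted p = 0.0754, 0 called over all miRNAs or adjusted over the list alone). No call was left with RLE, upper quartile or total count scaling, with the replicate block or without position 9 variants. The count was 0 without LJCgCN replicate 1 or any LJCg library, 1 without LJCgCN replicate 3 and 18 without LJCgCN replicate 2.

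The departure of the combined treatment from the sum of its parts was called for 5 miRNAs in LJ, 4 positive and 1 negative. PC-3p-85_54490, which fell under caffeine alone, stood at 22691 ± 6944 CPM with the fungus added (departure 2.39, SE 0.53, adjusted p = 0.0281). PC-3p-4889_2585 stood at 659.8 ± 158 CPM in the combination, 170.8 ± 67.7 after inoculation, 305 ± 93.4 under caffeine and 701 ± 39.4 at mock (3.14, SE 0.71, adjusted p = 0.0281). gma-miR403a_R-1_1ss20TC was at 79.6 ± 63.1 CPM in the combination and 1659 ± 1623 under caffeine alone (−6.10, SE 1.32, adjusted p = 0.0281). The small RNA machinery list had 1 of 12 members with a positive departure, 1 called and 3 when adjusted over the list alone (camera adjusted p = 0.000369, 0.940 with an estimated correlation). The other calls, PC-5p-1520_4860 (adjusted p = 0.0329) and PC-3p-283_14063 (5.61, SE 1.25, adjusted p = 0.0281), were position 9 variants. The called form held 38.4 and 28.4% of miR403a in LJCN replicates 1 and 2 and 2.1% in replicate 3, so its departure rests on libraries that stood apart in such forms; the list was not tested without both of them. The 5 calls fell to 0 without LJCK replicate 1 or 2, LJCg replicate 1 or 2, LJCN replicate 1 or 2, or LJCgCN replicate 1 or 3, to 1 without LJCK replicate 3 and to 2 without LJCN replicate 3.

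In ZC the combined treatment gave 15 calls against mock, all down, of which 11 were position 9 variants. The other 4 were rgl-miR7972_1ss14TG, at least 283-fold lower (adjusted p = 0.0283), mdm-MIR482c-p3_2ss12TA22TC (−5.42, SE 1.13, adjusted p = 0.0148), hbr-MIR6173-p3_3ss9TA17AG18GC (−6.27, SE 1.45, adjusted p = 0.0283) and mtr-miR168b_R-1 (−3.51, SE 0.94, adjusted p = 0.0477), the second and last chosen after their values were seen. All 4 were at their higher level in ZC where the libraries were of the high class. The largest changes among the variants were those of gma-MIR4995-p5_2ss9TA21GC (at least 386-fold lower), gma-MIR4995-p5_2ss9GC20GC (at least 280.1-fold) and PC-5p-1520_4860 (−9.44, SE 1.87). Against ZC inoculation alone 22 passed, 18 down, 14 of these position 9 variants, and 4 up. Those that rose were PC-5p-60986_244 (86.1 ± 22.7 CPM against 0, at least 14.5-fold, adjusted p = 0.0173), PC-3p-15934_1146 (47.1 ± 50.8 against 0, at least 7.90-fold, adjusted p = 0.0132), PC-3p-36356_497 (212 ± 30.7 against 34.1 ± 29.5, 2.57, SE 0.72, adjusted p = 0.048) and mtr-miR162_R+1 (301 ± 159.6 against 79.6 ± 39.0, 1.91, SE 0.55, adjusted p = 0.0491). rgl-miR7972_1ss14TG was at least 277-fold lower, the MIR4995 variants at least 576-, 412- and 92.4-fold, and PC-5p-1520_4860 fell by 8.93 on the log2 scale. ath-miR169a-3p_L+1_1ss13CA stood at 1338 ± 699 against 416 ± 229 CPM (adjusted p = 0.0824).

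The 15 calls against mock became 2 without any one of the ZCCgCN libraries, and 7, 6 and 9 without ZCCK replicates 1, 2 and 3. The 22 against inoculation became 10, 10 and 8 without ZCCg replicates 1, 2 and 3 and 4, 2 and 3 without ZCCgCN replicates 1, 2 and 3; 0 remained in either contrast with the library class as a term. ZCCgCN and ZCCN lie in the same class of libraries, and between them edgeR called 0 miRNAs (64 at an unadjusted p under 0.05, DESeq2 14, voom 5); this contrast was added after the data were seen. Its smallest p-values, each with an adjusted p of 0.187, were those of mtr-miR390 (3919.8 ± 1446 against 619 ± 416 CPM), mtr-miR166e-5p_1ss20GT (542 ± 428 against 72.6 ± 39.0), PC-3p-811_6744 (3304 ± 1937 against 1024 ± 213), PC-3p-69117_203 (64.0 ± 24.7 against 0) and the position 9 variant gma-miR394a-5p_1ss9CA. Departure from additivity in ZC had 0 calls by edgeR (46 at an unadjusted p under 0.05, DESeq2 10, voom 4), with PC-3p-15934_1146, PC-5p-121124_78, PC-3p-36356_497 and PC-3p-69117_203 at an adjusted p of 0.107 and vvi-MIR319b-p3_2ss6AT21CA at 0.137.

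The cultivars differed in their response to the combined treatment for 38 miRNAs, 37 of them with a lower log2 fold change in ZC and 24 position 9 variants (Fisher's exact p = 5.05e-20, on a class defined from the same libraries). rgl-miR7972_1ss14TG went from 0 to 674 ± 608 CPM in LJ and from 1211 ± 244 to 0 in ZC (adjusted p = 0.0015). mdm-MIR482c-p3_2ss12TA22TC went from 0 to 746 ± 625 in LJ and from 1957 ± 159.4 to 45.4 ± 30.6 in ZC (adjusted p = 6.03e-05). Both went with the library class, so neither difference can be assigned to the cultivars. PC-3p-66552_215, the call in the other direction, went from 99.96 ± 12.3 to 27.0 ± 23.6 CPM in LJ and from 0 to 53.1 ± 14.6 in ZC (adjusted p = 0.0305). The MIR4995 variants at position 9 had adjusted p-values of 0.000882 to 0.00558. The count was 24 without LJCK replicate 3 and 25 without ZCCgCN replicate 1.

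Resistant and susceptible leaves were compared at mock, which asks how the cultivars differ before any treatment. Of the 477 miRNAs 65 differed, 45 higher and 20 lower in ZC, and 63 of them had no overlap between groups. Of all tested miRNAs 35.0% had none, where chance gives 10%. All 18 position 9 variants among the calls were higher in ZC (Fisher's exact p = 4.97e-07). Among the other 47, the largest differences toward ZC were those of mdm-MIR482c-p3_2ss12TA22TC (1957 ± 159.4 CPM against 0, at least 339.9-fold, adjusted p = 0.000237), rgl-miR7972_1ss14TG (at least 210.4-fold, adjusted p = 0.0108), PC-3p-42752_405 (323 ± 93.2 against 0, at least 56.1-fold), PC-5p-63764_229 (311 ± 253 against 0, at least 54.1-fold, adjusted p = 0.00155 for both) and hbr-MIR6173-p3_3ss9TA17AG18GC (at least 45.4-fold, adjusted p = 0.00508). The MIR482c, miR7972 and MIR6173 forms stood far lower in ZCCN and ZCCgCN, which lie in the low class. Their differences at mock cannot be told apart from the library class. Position 9 variants of the rule, gma-miR394a-5p_1ss9CA, the MIR4995 forms and csi-miR164a-3p_2ss9CA10TG, were at least 538-, 287-, 208-, 43.5- and 46.2-fold higher. PC-5p-217_18505, on the minus strand of Scaffold1170 from 1280991 to 1281153, had the smallest p of all (11689 ± 677 against 675 ± 94.7 CPM, 4.11, SE 0.41, adjusted p = 7.81e-07); it lies outside the naming rule and was chosen after its values were seen.

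Lower in ZC than in LJ were ptc-MIR166n-p5_1ss9TC (0 against 296 ± 81.0 CPM, at least 46.3-fold, adjusted p = 0.000103), PC-3p-48707_338 (0 against 253 ± 91.7, at least 39.5-fold, adjusted p = 0.00063) and PC-3p-66552_215, PC-5p-81222_156, PC-3p-97320_115 and PC-5p-55520_280, at least 15.6-, 11.9-, 11.8- and 10.9-fold. PC-3p-16528_1110 had a log2 fold change of −5.16 (SE 1.44, adjusted p = 0.0239) and PC-3p-15934_1146 of −2.56 (SE 0.79, adjusted p = 0.0371). Among miRNAs with known families, bra-miR156e-3p_3ss3CT8CT15T- stood at 212 ± 83.7 against 1138 ± 236 CPM (−2.42, SE 0.60, adjusted p = 0.0109). mtr-miR167b-5p_R+1, the leading member of the auxin list, whose family targets auxin response factors, stood at 5839 ± 1428 against 16657 ± 5768 CPM (−1.51, SE 0.39, adjusted p = 0.0128). ath-miR858a_L-1R+1_1 stood at 4588 ± 1990.2 against 14135 ± 6054 CPM (−1.62, SE 0.53, adjusted p = 0.0424), and mtr-miR166c at 68564 ± 87495 against 6459 ± 1781 (3.41, SE 0.89, adjusted p = 0.0161). The SD of mtr-miR166c in ZC exceeds its mean, so its libraries lay far apart. Its sequence differs from the more abundant ppe-miR166a by a single base, at position 20.

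By list, auxin signalling had 2 members higher in ZC, 1 of them a position 9 variant, and 3 lower, all miR167 forms (6 of 21 with a higher fitted level; camera adjusted p = 0.200). NBS-LRR targeting had 2 higher, the MIR482c form and mdm-miR482a-3p_2ss9CG21TG (2208 ± 146 against 801 ± 225 CPM, 1.46, SE 0.46, adjusted p = 0.0371; list 0.833). The MIR482c form went with the library class. Leaf development had 9 higher and 1 lower of 37, with 34 of 37 at a higher fitted level and 10 passing when adjusted over the list alone (camera adjusted p = 0.119). Of the 9, 4 were position 9 variants, and aly-miR165a-3p_R+1_1ss9GC and gma-miR171j-5p_2ss8CT9TC carry a substitution at position 9 in their name. Another, mtr-miR166b_L+2R-2_1ss21CT, rose from 1126 ± 85.9 to 5733 ± 3100 CPM (2.35, SE 0.50, adjusted p = 0.00327). Small RNA machinery had mtr-miR168b_R-1 higher (1105 ± 409 against 37.4 ± 15.8 CPM, 4.85, SE 1.02, adjusted p = 0.00324; list 0.944). In ZC mtr-miR168b_R-1 held 42.4 to 47% of miR168b in ZCCK, but 2.71 to 6.44% in ZCCN and 3.86 to 4.81% in ZCCgCN, of the low class. Its difference at mock cannot be told apart from the library class. MYB and TCP targeting had mdm-MIR159d-p5_1ss3GC higher, at least 32.5-fold (list 0.598). Adult leaf had mtr-miR172b lower (1493 ± 376 against 3643 ± 1362 CPM, −1.29, SE 0.37, adjusted p = 0.0278; list 0.944). Juvenile leaf had 1 lower (list 0.833) and phenylpropanoid 2 lower, miR858a forms with equal counts (list 0.122). When position 9 variants were left out, 0 were called in the adult leaf and phenylpropanoid lists. The lists of copper, nutrient starvation, NF-YA and Arabidopsis PAMP-responsive miRNAs had 0 calls over all miRNAs by edgeR, with 5 of 9, 4 of 6, 2 of 8 and 4 of 8 members at a higher fitted level and camera adjusted p-values of 0.944, 0.912, 0.930 and 0.780. With an estimated correlation the adjusted p was 0.995 for every list of this comparison. Relative to TMM, scaling by total count moved the median log2 fold change by −0.41 and the upper quartile by −0.29. The 65 calls became 26, 30 and 36 without LJCK replicates 1, 2 and 3, and 35 without ZCCK replicate 3.

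Because mock libraries of the cultivars lie in different classes, the cultivars were also compared under caffeine, where all 6 libraries lie in the low class; this contrast was added after the data were seen. It gave 51 calls, 21 higher and 30 lower in ZC, of which 3 were position 9 variants (Fisher's exact p = 0.603). Of the 47 other calls at mock 6 had a substitution at position 9 in their name. Of the 47, 33 had the same direction under caffeine and 18 were called with it, 9 in each direction. Independent lists would share 1.24 up and 1.28 down among the 436 tested miRNAs that are not position 9 variants. The contrasts share no library, but both come from the same model and share its estimates of spread, so the lists are not fully independent. Of the 18 position 9 variants called at mock 0 were called under caffeine, but 8 of them were at 0 in every caffeine library of both cultivars and could not be called; the same held for 4 of the 47. PC-5p-63764_229, PC-3p-42752_405, PC-3p-70649_196, PC-5p-59288_254 and PC-3p-95107_120 were at 0 in LJ and at least 106-, 91.0-, 49.3-, 21.3- and 17.0-fold higher in ZC. ptc-MIR166n-p5_1ss9TC (0 against 375 ± 73.3 CPM, at least 64.4-fold, adjusted p = 8.5e-05), PC-3p-48707_338 (at least 66.9-fold) and PC-5p-81222_156 (at least 20.8-fold) were again lower in ZC. In the same contrast mtr-miR167b-5p_R+1 stood at 5844 ± 527 against 16769 ± 1644 CPM (−1.52, adjusted p = 0.0172). mtr-miR168b_R-1 and gma-MIR167k-p3_3ss9CA21TG22AG were called in opposite directions in the pair of contrasts. The 51 calls became 29, 21 and 28 without LJCN replicates 1, 2 and 3, and 20 and 18 without ZCCN replicates 1 and 3.

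**Figure D2:**
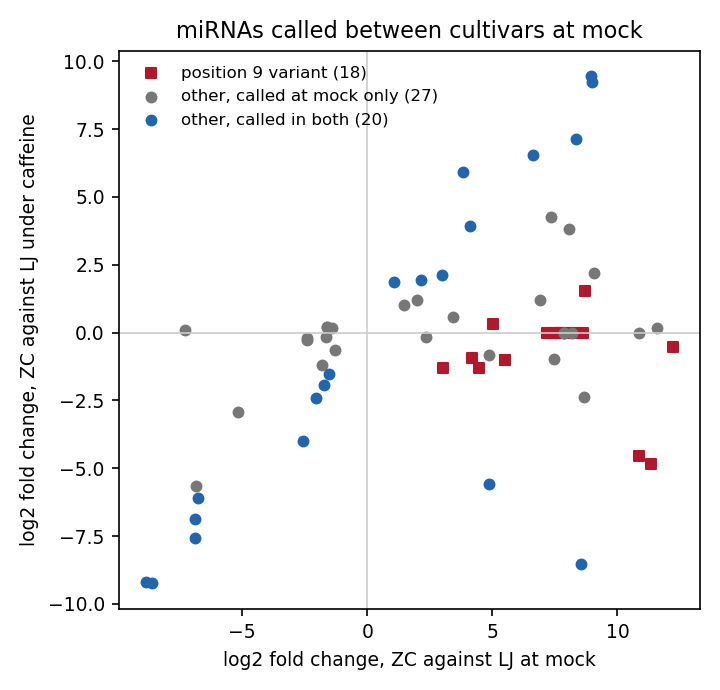
Fitted log2 fold change of ZC against LJ at mock (horizontal) and under caffeine (vertical) for the 65 miRNAs called at mock, with position 9 variants as squares (18), other miRNAs called at mock only as grey circles (27) and those called in both contrasts as blue circles (20). Of the blue circles 18 lie in quadrants of equal sign; the fitted values of miRNAs at 0 in one group depend on the prior count and are not bounds.

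The degradome asks which transcripts the miRNAs cleaved. The 6 deposited tables, each setting a treated library beside its mock, held 1156 distinct pairs of miRNA and transcript, 388 of them in all 6 tables. The 3 tables of a cultivar share its mock library, so a pair with reads in both mock libraries is in all 6 whatever the treated libraries held, and 373 of the 388 were such pairs. Reads in all 6 treated libraries were found for 136 pairs, and in all 8 libraries for 127. Tables of LJ held 1017 of the pairs and those of ZC held 722, with 583 in both. Libraries were not replicated, and totals implied by the tables ran from 14959429 reads (ZCCgCN) to 26670734 (LJCK). The read counts below describe single libraries, with no test between conditions. The pair with the most abundant miRNA was miR166a with REVOLUTA (CSS017546.1, position 574), with 440 reads in LJCK, 231 in LJCg, 730 in LJCN, 236 in LJCgCN and 51 to 92 in the ZC libraries. miR858a cleavage of TT2, a MYB regulator of proanthocyanidin synthesis (CSS009271.1, position 349), had 489 reads in ZCCg, 136 in ZCCK, 129 in ZCCgCN and 4 in ZCCN, against 38 in LJCK, 11 in LJCg, 10 in LJCgCN and 0 in LJCN. An R2R3 MYB transcript (CSS045240.1, position 336) cleaved by the same miRNA had 478 reads in ZCCg, 44 in ZCCK, 89 in ZCCgCN, 3 in ZCCN, 120 in LJCgCN and 16 to 21 in the other LJ libraries. ARGONAUTE1 (CSS028509.1, position 547), the target of miR168b, had 124 reads in LJCgCN, 49 in LJCK, 27 in LJCN and 12 in LJCg, and 1 to 13 in ZC. ARGONAUTE2 (CSS045705.1, position 3310), the target of miR403a, had 115 reads in LJCK, 48 in LJCg, 44 in LJCN and 0 in LJCgCN, and 4 to 8 in ZC. Another ARGONAUTE2 transcript listed for it (CSS045704.1, position 2585) had 5, 11, 23 and 0 reads in the same order, and 2 to 13 in ZC.

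Further pairs of named miRNAs were found at known kinds of target. miR159a was listed at GAMYB (CSS032054.1, position 1110) with 42 to 106 reads in LJ and 9 to 42 in ZC. A miR394a-5p position 9 variant was listed at F-box only protein 6 (CSS013937.1, position 478) with 164 reads in ZCCN, 98 in LJCgCN, 93 in LJCN, 25 in ZCCK, 22 in ZCCgCN, 15 in LJCK and 13 in LJCg and in ZCCg. A NAC transcript (CSS048404.1, position 649) listed for mtr-miR164a_1ss9CA had 701 reads in LJCg, 568 in LJCN, 72 in LJCK and 6 in LJCgCN, and 40 to 75 in ZC. Of all variant pairs in category 0, 16 lay at sites also listed for another sequence and 1 at a site listed for no other. Reads at shared sites cannot be credited to the variants. Of the 125 pairs that were in all 6 tables and in the best category in each, which category 0 in both mock libraries is enough to meet (109 of the 125), the 10 with the smallest p by the authors' Fisher test were 9 miR858 pairs, at TT2 and at CSS004315.1 (position 300), and miR393a with the auxin receptor AFB2 (CSS023432.1, position 1682; 323 reads in LJCK, 302 in ZCCK and 112 to 393 in the others). How ties were ordered was chosen after the tables were seen. The authors' p-values do not follow from the raw reads: by the authors' deposited tables, p was under 0.05 for 86.8 to 97.2% of the pairs, against 24.2 to 48.5% by a Fisher test of raw reads against library totals, so this ranking only selects pairs to describe. Sites at a clear cleavage peak (category 0) made up 25.2% of detected pairs in LJCK (exact 95% interval 21.9 to 28.7) and 40.7% in ZCCgCN (35.6 to 45.9), the lowest and highest of the 8 libraries; the others ran from 26.3% in ZCCg to 33.6% in LJCN. Several forms of a miRNA listed at a site share its reads, as the miR858 pairs at TT2 do. Pairs are thus not independent, and these intervals are too narrow. All intervals and floors cover counting error at most.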

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

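All explanations below and the values that test them were chosen after the results were seen. The library class was itself defined from the data, so tests that use it are not independent evidence.

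The difference between cultivars in the caffeine response was singled out because a test of the difference itself called 21 miRNAs, and the difference in the response to the combined treatment because it called 38. Of these, 11 and 24 were position 9 variants. In both contrasts the libraries of the groups cross the library classes, so a difference between cultivars and a difference between classes cannot be told apart for most of the calls. Without position 9 variants the counts were 4 and 6, and with the class as a term 17 and 2, of which 9 of the 17 were among the original 21.

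The larger share of position 9 variants in 8 libraries was weighed against 4 explanations. A cultivar allele is excluded, since 6 of the 12 ZC libraries were in the low class. Base-call errors at read position 9 would place the mismatch at position 9 of the read whatever the start of the miRNA. There were 70 one-base matches with a shifted 5′ end, some of them of the same sequence. Of these, 20 lay at position 9 of the variant, where the next highest position had 4. Some of the 20 are forms with equal counts. Counted along the more abundant sequence, 8 lay at position 9, also the highest there. The larger count at the variant's own position 9 may point to the sequencing run. For the treatment of the leaves, LJCgCN replicate 2 had a share of 1.617% while replicates 1 and 3 of the same group had 14.7 and 19.7%, a split that cannot rule treatment in or out.

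Whether the variants are RNAs that guide cleavage could not be settled either. At degradome sites listed for no other sequence, 1 of 39 variant pairs was in category 0 (2.56%, exact 95% interval 0.0649 to 13.5) against 32 of 637 others (5.02%; Fisher's exact p = 0.714). The class boundaries follow the borders of the groups except in LJCgCN, and the sequencing run of each library is not given in the sources used here.

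The 29 calls of caffeine against mock in ZC could come from the position 9 class or from a caffeine response. Position 9 variants were 17 of the 29 calls (Fisher's exact p = 5.9e-13), but this value is built from the same libraries and cannot separate the explanations. With the class as a term 1 miRNA was called, and it was none of the 29. That term is estimated only from the LJCgCN libraries, so neither explanation can be excluded.

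rgl-miR7972_1ss14TG was at 829 to 1442 CPM in 8 libraries and at 0 in 16, where 3 counts correspond to at most 22.7 CPM. Detection went with the high class in all 24 libraries, which is consistent with a feature of the libraries. The degradome held its site in DEMETER, a DNA glycosylase that removes methylated cytosine (CSS041252.1, position 881). Of the 5 conditions in which the miRNA was at 0 in every library, 4 had this site in category 0, which were LJCK (30 reads), LJCg (78 reads), LJCN (172 reads) and ZCCgCN (14 reads). ZCCN, the remaining such condition, had 11 reads there in category 2. By single unreplicated libraries, the site was thus cleaved in the 4 conditions. Whether this miRNA guided the cleavage cannot be told, since another small RNA could guide it.

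Regrouping the libraries of each comparison asks how often other groupings of the same libraries give as many calls. Mixed groups still hold any real difference, which adds to their spread, so other splits give no rate of calls without one. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split had 0 calls for LJCg against LJCK (10 of 10 splits had as many, highest other 0), 5 for LJCN (1 of 10, highest other 2), 11 for LJCgCN against LJCK (1 of 10, highest other 0) and 3 for LJCgCN against LJCg (3 of 10, highest other 5). It had 0 for ZCCg (10 of 10, highest other 2), 29 for ZCCN (1 of 10, highest other 0), 15 for ZCCgCN against ZCCK (1 of 10, highest other 0), 22 for ZCCgCN against ZCCg (1 of 10, highest other 0) and 0 for ZCCgCN against ZCCN (10 of 10, highest other 0). Between cultivars it had 65 at mock (1 of 10, highest other 0) and 51 under caffeine (1 of 10, highest other 5).

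For the contrasts of 4 groups 100 splits were run, the real split and others drawn at random from a larger set. Their highest counts hold for these splits only. As many calls as the real split came in 100 of 100 for the cultivar difference in the response to the fungus (0 calls, highest other 1) and for additivity in ZC (0 calls, highest other 6). Exchanging ZCCg with ZCCgCN whole gave 66 calls for additivity in ZC. Among the other splits with a pair of groups kept whole, counts reached 5 for the response to the fungus and 11 for additivity in ZC. For the cultivar differences under caffeine (21 calls) and under the combination (38 calls) 1 of 100 had as many, with 18 and 35 as the highest other. The splits with 18 and 35 calls keep the ZC groups whole and mix those of LJ, and that with 35 exchanges LJCgCN replicate 2 with LJCK replicate 2, which leaves the high class libraries of LJCgCN together. Over all 20 splits of the LJ libraries with ZC whole, 1 had as many calls in either contrast, with 18 and 37 as the highest other. Labels were exchanged only within the pair of groups of each cultivar, and mixed groups still hold any real difference. These shares therefore cannot exclude a random origin of the counts, nor that the counts come from the ZC groups or the classes. They do not test the difference between cultivars. For additivity in LJ (5 calls) 3 of 100 had as many, with 8 as the highest. The split with 8 keeps all groups whole and exchanges LJCg with LJCgCN. With LJCN and LJCK whole 4 of 20 splits had as many, so a random origin of these 5 calls stays open.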

How the results depend on the processing

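Settings that involve position 9, the authors' constants, sums over loci, or leaving out miR2916 and miR5368 were chosen after the results were seen, as were the contrasts of ZCCN with LJCN and of ZCCgCN with ZCCN. Within 1.5 times of their count in every comparison stayed the fits with the authors' constants, a filter at a mean of 10 CPM, library sizes without the most abundant miRNA, an added limit of a 2-fold change, and without miR2916 and miR5368. The alternative for a table holding only normalized values did not apply. Where a count moved, the cause was not tested. Depth sets the floors of 4.26 to 6.40 CPM for groups at 0; fits at other depths were not run. Fits with only the LJCgCN library of the low class leave that group 1 library, so the spread comes from the other groups and fewer calls are expected whatever the cause.

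Lists called by camera were 3, and 0 with an estimated correlation, 8 without position 9 variants and 23 with the class as a term.

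For LJCg against LJCK (0 calls) DESeq2 gave 10 and voom 1. For LJCN against LJCK (5) DESeq2 gave 23, voom 3, sums by family 3 and the fit without position 9 variants 9. There only the groups compared gave 7, of which 2 were among the 5. For LJCgCN against LJCK (11) DESeq2 gave 24, total count 7, sums by family 0, only the groups compared 0, without position 9 variants 1, the class term 2 and only the LJCgCN library of the low class 2. For ZCCg against ZCCK (0) DESeq2 gave 12. For LJCgCN against LJCg (3) DESeq2 gave 20 and voom 1. There 0 were called with RLE, upper quartile, total count, the replicate block, all lines, 20 to 22 nt, sums by family, sums over loci, without position 9 variants, the class term, only the groups compared, and only the LJCgCN library of the low class.

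For ZCCN against ZCCK (29) DESeq2 gave 68, voom 63, all lines 50, sums over loci 16, total count 15, 20 to 22 nt 12, sums by family 3, without position 9 variants 3 and the class term 1. For ZCCgCN against ZCCK (15) voom gave 48, DESeq2 25, only the groups compared 23, sums over loci 9, the replicate block 6, sums by family 2, without position 9 variants 1 and the class term 0. For ZCCgCN against ZCCg (22) voom gave 55, only the groups compared 41, sums over loci 13, the replicate block 11, sums by family 6, without position 9 variants 2 and the class term 0. For ZCCgCN against ZCCN (0) DESeq2 gave 14 and voom 5.

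For ZCCK against LJCK (65) voom gave 109, the replicate block 39, sums by family 37, without position 9 variants 37 and the class term 28. For ZCCN against LJCN (51) only the groups compared gave 19, no filter 28, 20 to 22 nt 30 and the replicate block 30. For the cultivar difference in the response to the fungus (0) DESeq2 gave 5; for caffeine (21) DESeq2 gave 48, voom 35, without position 9 variants 4 and sums by family 2; for the combination (38) 20 to 22 nt gave 25, sums by family 9, only the LJCgCN library of the low class 9, without position 9 variants 6 and the class term 2. For additivity in LJ (5) DESeq2 gave 15, voom 2, no filter 2, without position 9 variants 1, and total count, the replicate block, only the groups compared, the class term and only the LJCgCN library of the low class 0. For additivity in ZC (0) DESeq2 gave 10 and voom 4.

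Leaving out each library in turn gave 2 to 17 lists. The calls ranged over 0 to 0 (LJCg against LJCK), 3 to 11 (LJCN), 0 to 21 (LJCgCN against LJCK), 0 to 18 (LJCgCN against LJCg), 0 to 2 (ZCCg), 2 to 25 (ZCCN against ZCCK), 2 to 9 (ZCCgCN against ZCCK), 2 to 10 (ZCCgCN against ZCCg), 0 to 0 (ZCCgCN against ZCCN), 26 to 49 (ZCCK against LJCK) and 18 to 35 (ZCCN against LJCN). For the cultivar differences they were 0 to 2 (fungus), 8 to 24 (caffeine) and 24 to 55 (combination), and for additivity 0 to 7 in LJ and 0 to 0 in ZC.

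For 107 fold changes of miRNAs named in the report, the settings run were RLE, upper quartile, total count, no filter, the replicate block, without position 9 variants, the class as a term, and leaving out each library. Those that became weaker were 5, 7, 18, 16, 27, 19 (against 46 that stayed the same) and 68 (against 36), and 294 with a library left out (against 515). Directions were kept except with the class as a term, where PC-5p-1520_4860 had 2.03 in ZCCgCN against ZCCK and 2.54 against ZCCg, and rgl-miR7972_1ss14TG had 0 in LJCgCN against LJCg. Replicate numbers do not pair the libraries: deviations of libraries with the same number correlated at −0.021 on average (−0.341 to 0.452), and 9 of 24 libraries correlated best with one of their own number.

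The 21 nt share was 69.5%, 71.6% over all lines and 58.5% without the most abundant miRNA. The top sequence of each library held 27.2% on average, and 16.72% without that miRNA. The 1156 degradome pairs were 1149 at an authors' p under 0.01 in any table, 882 in categories 0 to 2, and 764 with the transcript as the unit. The 388 pairs in all 6 tables became 167 at an authors' p under 0.01 in each and 292 in categories 0 to 2.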

Other observations

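The comparisons below were chosen after their values were seen and were not tested further.

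Some miRNAs belonged to 1 cultivar under every treatment. ptc-MIR166n-p5_1ss9TC, from the other arm of a hairpin of the miR166 family, was detected in all 12 LJ libraries (397.8 ± 147 CPM, SD, n = 12) and in 0 of 12 ZC libraries, at least 290.0-fold apart by a floor of 1.37 CPM from 3 counts over the 12 libraries (1.21 CPM over those of LJ), and PC-5p-55520_280 in 12 and 0 (56.4 ± 28.1 CPM in LJ, at least 41.1-fold). PC-5p-63764_229 (378 ± 250.3 CPM, at least 313-fold) and PC-5p-59288_254 (158 ± 72.0, at least 131-fold) were detected in all 12 ZC and in 0 of 12 LJ libraries. PC-3p-48707_338 was detected in 12 LJ libraries and 1 ZC library. The hairpins lie on Scaffold4015 (48182 to 48288, plus strand), Scaffold5417 (169563 to 169675, plus), Scaffold364 (706810 to 706967, minus), Scaffold6418 (88342 to 88445, plus) and Scaffold1689 (1183299 to 1183487, plus), in coordinates of a build not given in the sources used here.

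ptc-MIR166n-p5_1ss9TC and PC-5p-12215_1404 were given the same hairpin and arm on Scaffold4015 and differ by 1 base, T in PC-5p-12215_1404 and C in the other at position 14. They differed between cultivars in opposite directions. At mock PC-5p-12215_1404 stood at 1125 ± 84.2 CPM in ZC and 141 ± 25.6 in LJ (2.98, SE 0.54, adjusted p = 0.00102 by edgeR), and under caffeine its log2 fold change was 2.13, while ptc-MIR166n-p5_1ss9TC was at 0 in ZC in both. Such a pair could reflect a base that differs between the cultivars at this locus, which needs genome sequence of the cultivars; a cultivar allele was excluded for the position 9 class, where 6 ZC libraries were in the low class, but not for this pair.

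Forms lacking the last base at the 3′ end made up different shares of some miRNAs in single libraries. Of 12 such pairs 5 had the shorter form above all LJCK libraries in both LJCN replicates 1 and 2. The shorter form of mtr-miR168b was 40.6, 36.1 and 2.44% in LJCN replicates 1, 2 and 3, and that of gma-miR403a_1ss20TC 38.4, 28.4 and 2.1%. The shorter form of ath-miR858a_L-1R+1_1 was 21, 14.2 and 0.997% in the same libraries. That of mtr-miR396b-3p_2ss7TG8AG was 24.1, 20.9 and 7.7% there and 3.35 to 4.35% in LJCK, but also 21.1% in LJCgCN replicate 2, 26.6% in ZCCK replicate 3 and 30.7% in ZCCgCN replicate 1. For mtr-miR168b the share was 42.4, 44.1 and 47% in ZCCK, 42.9, 43.1 and 43.7% in ZCCg, and 29.6 and 45.2% in LJCgCN replicates 1 and 3, the libraries of the high class. It was 2.29% in LJCgCN replicate 2, 6.44, 2.71 and 5.38% in ZCCN, 4.81, 3.86 and 4.56% in ZCCgCN, 2.83, 5.79 and 2.61% in LJCg and 0.803 to 1.79% in LJCK, so outside LJCN it went with the library class.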
